A study of Bos taurus with 27 samples.

How the data were processed

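RNA from bovine embryos was measured in 27 libraries made with the SMART-Seq v4 kit for low input and Nextera XT tagmentation, per the labels' protocols. The deposited values are FPKM per assembled transcript, made by the authors. Per the submitters' processing notes the tools were FastQC 0.10.1, TopHat2 2.1.0 and StringTie (version not given). The genome build, the annotation, the role of each tool and any filter are not given in the sources used here. The kit is not stated to keep the strand of the RNA, so a locus and an antisense partner cannot be told apart.

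The table held 173449 transcripts whose identifiers name a locus and a transcript of that locus, and nothing else. A reference table of RefSeq genes (assembly ARS-UCD2.0) shares no identifier with it, so 0 of them were matched, and no gene name, position or organism is given for any locus. The gene lists written before the data were examined, the share of mitochondrial transcripts, sums over Y-linked genes and over markers of other cell types, and genes named by symbol were therefore not analysed here. Of the 116933 loci, 100871 had 1 transcript and 31772 were at 0 in each library. Values equal to those of another locus in each library were seen at 6782 loci that were above 0 in some library, and such loci can hold the same reads. The number of columns of per-sample values left unused was 0, and no pair of the 27 columns was identical, with Spearman correlations between libraries from 0.571 to 0.865.

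Each locus was represented by its transcript with the highest mean FPKM over all libraries, a choice made after the table was seen. Loci with at least 1 FPKM in at least 8 libraries were kept. Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with all 3 groups in one fit, no covariate, and empirical Bayes moderation with trend and robust settings. Tests were two-sided and adjusted by Benjamini and Hochberg over the 13461 loci, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low loci. A fold of at least 2 or 8 means a log2 fold change of at least 1 or 3 in absolute value.

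Single values per library were compared by exact two-sided permutation tests over each of the 12870 assignments (8 against 8) or 75582 (8 against 11). They were adjusted over 3 pairs for detected loci, over 3 pairs for the share of the 10 highest loci and over 10 tests for the measures added after the data were seen: relative depth, FPKM sum, spread within the group and position between the IVF stages. These used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The distance behind the spread was corrected for the size of the group.

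FPKM hides the number of reads, so no count test was run. Low values are whole reads divided by length and depth, and the ratio of a low transcript between libraries piles up at ratios of small whole numbers. Transcripts above 0 in at most 9 libraries with values of 0.05 to 5 FPKM gave a depth for each library relative to the median library. For 94.9% of library pairs the ratio lay within 0.03 log2 of the fitted depths, which were fitted to those same ratios. In the median pair, 13.6% of the low transcripts measured in both libraries lay close to the main ratio of the pair. Relative depths ran from 0.336 to 1.667. Total depth is unknown, so no interval for counting error is given.

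The fit was tested on simulated data made by shuffling the residuals of the 13461 tested loci over the libraries. Among loci with a mean of at least 2 FPKM, 100 were changed at each of 2 sizes. At a log2 fold of 1 it recovered 24%, 25% and 22% of the changed loci in the comparisons late against 8-cell IVF, parthenote against 8-cell IVF and parthenote against late 8-cell IVF. At a log2 fold of 2 it recovered 72%, 80% and 79%, with 2, 0 and 0 false calls in all. The depth estimate was tested on simulated whole-read counts with simulated transcript lengths, with an error of at most 0.0002 log2. Its premise of whole reads held there by construction, so the error in the real libraries may be larger.

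The rule for named genes asked for a symbol and an average of at least 10 FPKM in the higher group, with at least 75% of its libraries above the median of the lower group. The symbol could not be applied, and 2416, 83 and 2527 loci met the rest of the rule in the 3 comparisons. Only the 2 of these with the highest and the 2 with the lowest fold change of late against 8-cell IVF are named. Loci that the filter removed were not ranked, among them most of those that turned on. The abundance classes, the limits of 0.1 and 1 FPKM for loci that turned on or off (counted with no filter, tests adjusted over 85161 loci), the run of locus numbers and the position measure were chosen after the data were seen.

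Other settings fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, rescaling to a common sum, median-of-ratios factors, quantile normalization, array weights, the compared groups alone, the replicate number as a block, a fold of at least 2 and each library left out. Settings added later were each transcript tested, the sum over the transcripts of a locus, replicates 1 to 8 alone, the loci without a run of neighbouring numbers, the position on abundant loci, and the overlaps without late 8-cell IVF replicate 1 or with no filter. Overlaps between comparisons that share a group are given with independent lists (the product of the list lengths over the loci tested), with 100 simulations that shuffled residuals over libraries, and with the shared libraries split into 2 parts.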

Results

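Polyadenylated RNA was sequenced from bovine embryos cultured at 38.5 C in 3 groups: 8 libraries of in vitro fertilised (IVF) embryos at the 8-cell stage, 8 libraries of IVF embryos late in the 8-cell stage, and 11 libraries of parthenotes at the 8-cell stage. Both IVF groups were first-generation crosses of Bos taurus and Bos indicus, whereas the parthenotes were Bos taurus. A parthenote develops from an oocyte activated without sperm and so carries maternal chromosomes alone. The series concerns embryonic genome activation, the stage at which an embryo starts to transcribe its own genes while RNA stored in the oocyte is degraded. The labels do not say whether a library came from 1 embryo, 1 cell or a pool, nor whether replicates came from separate cultures, so the p-values measure the spread between these libraries. The 8-cell IVF libraries carry the request number 18062 and the libraries of both other groups carry 19058.

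The deposited table gave FPKM (fragments scaled by transcript length and library total) for 173449 assembled transcripts at 116933 loci. The files pair none of these identifiers with a gene name, so loci are described here as groups and by level. Of all loci, 13461 reached 1 FPKM in at least 8 libraries and were tested. The number of loci at 1 FPKM or more was 12239 ± 850 (SD, n = 8) in 8-cell IVF, 11354 ± 1171 (SD, n = 8) in late 8-cell IVF and 13195 ± 1051 (SD, n = 11) in parthenotes. Parthenotes exceeded late 8-cell IVF by 1841 loci (exact two-sided permutation test, p = 0.00187, adjusted p = 0.0056 over 3 pairs). That difference was 154 loci at a minimum of 5 FPKM (adjusted p = 0.239, exact permutation test). The difference of 955 loci between parthenotes and 8-cell IVF did not pass (adjusted p = 0.0701, exact permutation test), but it did at minimums of 0.1 FPKM (2305 loci, adjusted p = 0.0461) and 5 FPKM (324 loci, adjusted p = 0.015), both by exact permutation tests. The difference between late and 8-cell IVF did not pass either (adjusted p = 0.107, exact permutation test). The 10 highest loci took 15.9% ± 1.68 (SD, n = 8) of the FPKM sum in 8-cell IVF, 14.8% ± 2.22 (SD, n = 8) in late 8-cell IVF and 14.04% ± 3.09 (SD, n = 11) in parthenotes, with no pair past the threshold (lowest adjusted p = 0.422 over 3 pairs, exact permutation test).

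Total read numbers per library are unknown from FPKM, but steps of whole reads among the low values gave depths relative to a library at 1. Relative depth was 0.779 ± 0.0663 (SD, n = 8) in 8-cell IVF, 1.15 ± 0.432 (SD, n = 8) in late 8-cell IVF and 1.04 ± 0.210 (SD, n = 11) in parthenotes. Parthenotes were deeper than 8-cell IVF (difference 0.265, exact permutation test, adjusted p = 0.012 over 10 tests), and the shallowest library was late 8-cell IVF replicate 6 at 0.336. The counts of detected loci stand beside these unequal depths.

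Late 8-cell IVF embryos were first compared with 8-cell IVF embryos, which asks how the transcriptome changes within the stage at which the bovine embryonic genome becomes active. Most of the tested transcriptome differed: 2891 loci were higher and 5923 lower in late embryos, together 65.5% of the loci tested. The excess of lower loci did not hold without the filter on low values, where 7074 were higher and 7094 lower among 85161 loci. Only 7 late libraries carried the late profile (below), so a locus silent elsewhere could hardly reach 1 FPKM in 8 libraries, while one silent in late embryos alone passed easily. The loci that rose held 10.1% ± 0.778 (SD, n = 8) of the FPKM sum of 8-cell IVF libraries and 44.9% ± 13.9 (SD, n = 8) of that of late libraries. The loci that fell went from 60.5% ± 2.09 (SD, n = 8) to 20.1% ± 16.7 (SD, n = 8). These loci were chosen on the same libraries, so the shares describe the size of the change and are not independent evidence of it. Late 8-cell IVF replicate 1 stood apart from its group with shares of 11.7% and 60.1%. Without it the late means were 49.7% ± 3.78 (SD, n = 7) and 14.4% ± 4.73 (SD, n = 7).

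**Figure D1:**
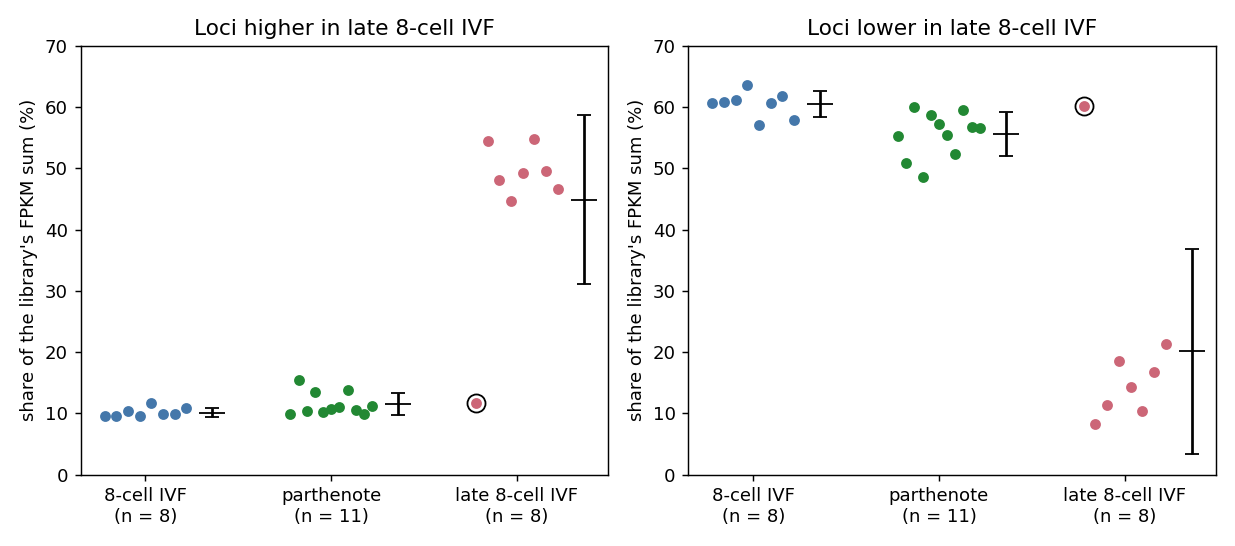
Share of each library's FPKM sum (%) held by the loci higher (left) or lower (right) in late 8-cell IVF than in 8-cell IVF. Points are libraries, bars are the mean ± SD of the group and the ring marks late 8-cell IVF replicate 1, which at 11.7% and 60.1% lies with the 8-cell groups while the other late libraries lie at 44.7% to 54.8% and 8.28% to 21.4%.

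The changes were large in both directions. At a fold of at least 2 on the log2(FPKM + 1) scale, 2019 loci were higher and 3342 lower in late embryos, and 219 were higher and 102 lower by a fold of at least 8. The median log2 fold change was 1.36 among the loci that rose and -1.08 among those that fell. Loci turned on, from a median under 0.1 FPKM at the 8-cell stage to at least 1 FPKM in late embryos, and loci turned off, the opposite, were counted without the filter, which removes most of the former. Of 85161 loci, 1096 turned on, to a median of 1.92 FPKM, and 865 turned off, of which 121 and 770 passed the filter. Tested with the filtered loci alone, 131 turned on and 919 turned off, so that contrast was set by the filter. In 1442 loci the libraries of the 2 groups did not overlap at all, against 2.09 loci, or 0.0155%, by chance. Without late 8-cell IVF replicate 1, the count without overlap was 4749 and 367 loci were higher and 173 lower by a fold of at least 8.

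By abundance, among 5482 loci with a mean under 2 FPKM, 13.6% were higher and 44.8% lower in late embryos, and among 2101 loci with a mean of 10 to 100 FPKM 29.2% were higher and 43.4% lower. Of the 181 loci at 100 FPKM or more, 48 were higher and 94 lower. Loci assembled as 1 transcript were higher in 17.4% and lower in 42.1% of 5578 cases. Those with 5 or more transcripts were higher in 26.6% and lower in 45.2% of 3333 cases. Differences between these classes were not tested, and the filter bears on the shares of the low classes. At 99 of the 6476 loci with several tested transcripts, 1 transcript rose while another fell. Transcripts of a locus share reads, so such pairs are uncertain.

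Locus MSTRG.6736 was nearly silent at the 8-cell stage, at 0.117 FPKM ± 0.234 (SD, n = 8), and reached 274 FPKM ± 167 (SD, n = 8) in late embryos, a log2 fold change of 7.06 (SE 0.74, limma, adjusted p = 2.5e-08). Locus MSTRG.28318 went from 2.14 FPKM ± 4.84 (SD, n = 8) to 336 FPKM ± 233 (SD, n = 8), a log2 fold change of 6.49 (SE 1.07, limma, adjusted p = 9.6e-06). Locus MSTRG.59785 fell from 543 FPKM ± 174 (SD, n = 8) to 102.9 FPKM ± 225 (SD, n = 8), a log2 fold change of -4.56 (SE 0.72, limma, adjusted p = 5.2e-06). Locus MSTRG.59787 fell from 99.3 FPKM ± 51.2 (SD, n = 8) to 12.4 FPKM ± 26.7 (SD, n = 8), a log2 fold change of -4.29 (SE 0.62, limma, adjusted p = 1.8e-06). Both rising loci were above every 8-cell IVF library in 7 of 8 late libraries, and MSTRG.59785 and MSTRG.59787 were below every 8-cell IVF library in 7 and 6 of 8. In late 8-cell IVF replicate 1, MSTRG.6736 was at 0.406 FPKM, MSTRG.28318 was listed at 0, MSTRG.59785 was at 656 FPKM and MSTRG.59787 at 77.6 FPKM. Without this library the log2 fold changes were 8.02, 7.54, -5.26 and -4.90, and the late means of MSTRG.59785 and MSTRG.59787 were 23.8 FPKM ± 23.4 and 3.14 FPKM ± 5.05 (SD, n = 7). The 8-cell IVF mean of MSTRG.6736 was 0.0359 FPKM without replicate 7 and that of MSTRG.28318 was 0.441 FPKM without replicate 5. The numbers 59785 and 59787 lie close together, and reads that such loci could share were not separated.

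**Figure D2:**
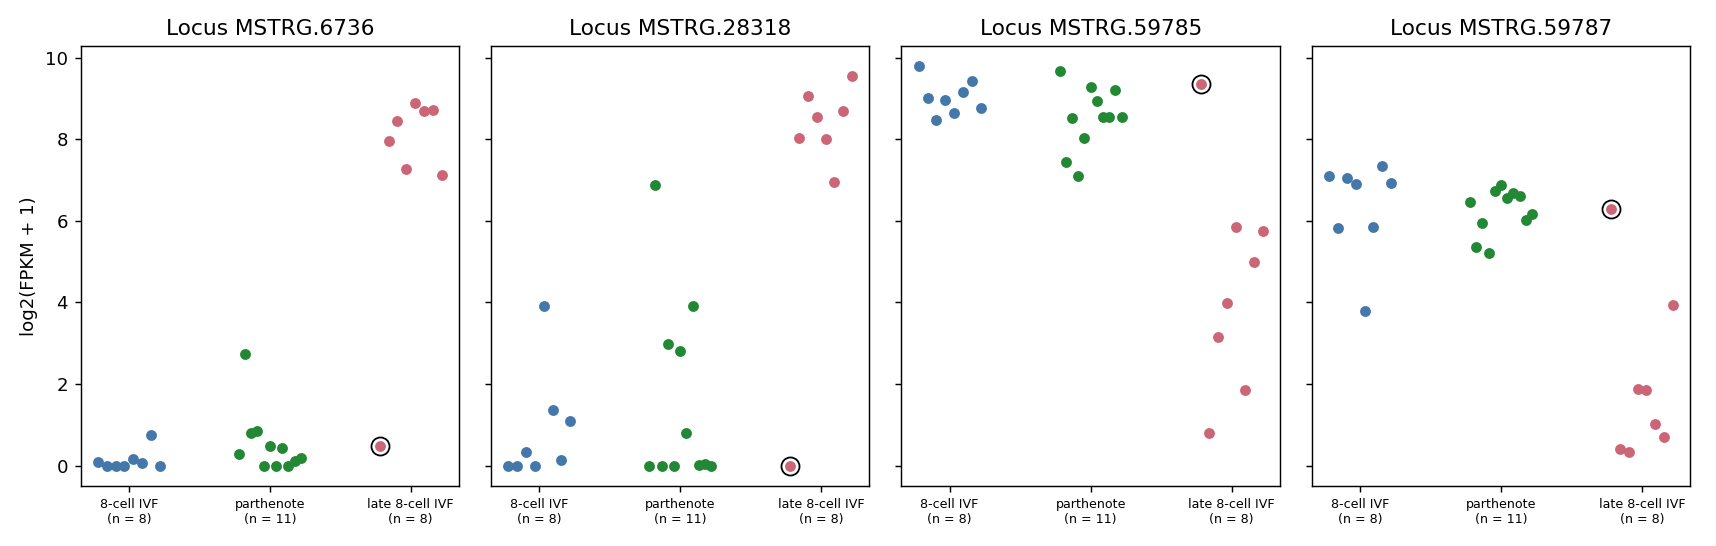
FPKM of 4 loci in each library on the log2(FPKM + 1) scale, by group, with each point a library. MSTRG.6736 and MSTRG.28318 were high and MSTRG.59785 and MSTRG.59787 low in the late 8-cell IVF libraries other than replicate 1 (ringed), whose values, 0.406, 0, 656 and 77.6 FPKM, lie in or near the range of the 8-cell groups.

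The median log2 fold change of all tested loci was -0.45, but 0.00 with no filter, and it depends on how libraries are scaled: -0.89 after rescaling each library to the same sum, -0.32 with median-of-ratios factors and -0.11 after quantile normalization. The split between directions moved with it to 3596 higher and 3948 lower loci under quantile normalization. No locus called under both the deposited scale and any of these scalings changed direction, with 2807 higher and 3863 lower calls shared with quantile normalization. The request number separates the same libraries as this comparison, and no request holds both groups. The parthenotes, of the same request as the late libraries, differed from 8-cell IVF at 361 loci with a median log2 fold change of 0.03, and within that request parthenotes and late embryos differed at 9560 loci.

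Parthenotes were next compared with IVF embryos at the 8-cell stage, which asks how embryos without a paternal genome differ at the same cell number. In the main fit 289 loci were higher and 72 lower in parthenotes, 2.7% of the loci tested, and the median log2 fold change of all loci was 0.03. Other settings gave from 90 loci (no filter) to 1693 (array weights), as set out below. The median change among the called loci was 1.06 upwards and -1.04 downwards, and at a fold of at least 2 there were 163 higher and 40 lower loci. No locus passed with a fold of 8 (limma, 2488 loci at an unadjusted p under 0.05 with any fold). By abundance, 75 loci with a mean under 2 FPKM were higher and 52 lower, and 165 were higher and 14 lower at a mean of 2 to 10 FPKM. At 10 to 100 FPKM there were 48 higher and 6 lower loci. Of the 181 loci at 100 FPKM or more, 1 was higher and 0 lower by limma.

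The loci that separated the IVF stages took shares in parthenotes closer to those in 8-cell IVF than to those in late embryos. Those higher in late embryos held 11.5% ± 1.86 (SD, n = 11) of the FPKM sum and those lower in late embryos held 55.6% ± 3.61 (SD, n = 11). Locus MSTRG.6736 was at 0.766 FPKM ± 1.65 (SD, n = 11), MSTRG.28318 at 13.05 FPKM ± 34.4 (SD, n = 11), MSTRG.59785 at 415 FPKM ± 202 (SD, n = 11) and MSTRG.59787 at 79.2 FPKM ± 26.7 (SD, n = 11). Parthenote replicate 2, at 5.67 and 116 FPKM, carried the means of MSTRG.6736 and MSTRG.28318. Without it they were 0.275 FPKM ± 0.3003 and 2.77 FPKM ± 4.76 (SD, n = 10). Their medians over the 11 parthenotes were 0.212 and 0.038 FPKM. MSTRG.6736 reached 1 FPKM in 7 late libraries and in this parthenote alone. It passed the filter of 8 libraries only through that value, which the choice of locus therefore fixed. None of the 4 passed the threshold against 8-cell IVF in limma (adjusted p = 0.80, 0.75, 0.74 and 0.94, with 2488 of all loci at an unadjusted p under 0.05).

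Of the 72 loci lower in parthenotes, 32 lay in a single run of locus numbers from 102680 to 103520, against 1.13 expected from the share of tested loci in the surrounding window. Each of the 32 was assembled as 1 transcript. Their mean level was 2.36 FPKM ± 0.883 (SD, n = 8) in 8-cell IVF, 0.437 FPKM ± 0.372 (SD, n = 11) in parthenotes and 0.727 FPKM ± 0.514 (SD, n = 8) in late 8-cell IVF. The run was noticed in the results of this comparison. Without its surrounding window, 246 loci were higher and 35 lower in parthenotes.

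**Figure D3:**
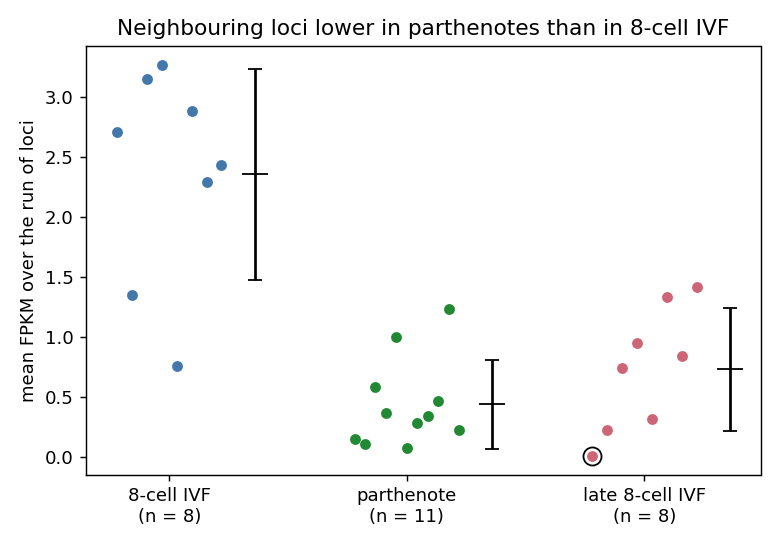
Mean FPKM over the 32 loci numbered 102680 to 103520 that were lower in parthenotes than in 8-cell IVF, with points for libraries and bars for the mean ± SD of each group. The 8-cell IVF libraries span 0.752 to 3.26 FPKM, the parthenotes 0.071 to 1.23 FPKM and the late 8-cell IVF libraries 0.007 (replicate 1, ringed) to 1.42 FPKM.

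The count of 361 loci depended on the libraries and the model. It was 718 without late 8-cell IVF replicate 1, which enters through the shared estimate of the spread, 1184 with the 2 compared groups alone and 1693 with array weights. Without 8-cell IVF replicate 1, 2, 5, 6 or 7 it was 139, 190, 192, 209 and 187, and without parthenote replicate 6 or 7 it was 221 and 236. Median-of-ratios factors gave 182 higher and 79 lower loci and quantile normalization 397 and 275. With no filter on low values, 33 loci were higher and 57 lower. The request number and the breed cross separate the same libraries as this comparison, so neither can be told apart from the lack of fertilisation.

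Parthenotes were last compared with late 8-cell IVF embryos, within request number 19058. In this comparison 6811 loci were higher and 2749 lower in parthenotes, 71.02% of those tested. With no filter 8331 were higher and 7574 lower among 85161 loci, so most of this excess too came with the filter. At a fold of at least 2 there were 3564 higher and 1823 lower loci. Against late embryos, MSTRG.6736 and MSTRG.28318 were lower in parthenotes by log2 fold changes of -6.66 (SE 0.68, limma, adjusted p = 2.1e-08) and -5.76 (SE 0.99, limma, adjusted p = 1.6e-05). MSTRG.59785 and MSTRG.59787 were higher by 4.06 (SE 0.66, limma, adjusted p = 8.4e-06) and 4.18 (SE 0.58, limma, adjusted p = 9.3e-07).

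Of the 1096 loci that turned on between the IVF stages when counted without the filter, 899 also had a median under 0.1 FPKM in parthenotes and 5 had a median of at least 1 FPKM. Of the 865 loci that turned off, 505 had a median of at least 1 FPKM in parthenotes and 31 a median under 0.1 FPKM. The filtered loci are not used here, because passing it depends on the parthenotes themselves. At 105 loci 1 transcript was higher and another lower in parthenotes than in late embryos. The median log2 fold change of all tested loci was 0.55, against 1.002, 0.39 and 0.13 under rescaling to the same sum, median-of-ratios factors and quantile normalization. With no filter it was 0.02, a value that loci at 0 in most libraries hold near 0. Quantile normalization gave 3765 higher and 3579 lower loci, and 4 loci called both ways had opposite directions. The breed cross differs between these groups as well.

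Calls were then set against each other to see which group stood apart. Late 8-cell IVF was higher than both 8-cell groups at 2430 loci and lower than both at 5295, where independent lists of the same lengths would share 590 and 2997. Quantile normalization gave 3001 and 2904 and no filter 6325 and 5171, so the majority of lower loci did not hold under either. With the late libraries split so that each comparison used its own part, the counts were 1885 and 3824 for one assignment (independent lists 467 and 2114) and 1912 and 3915 for the other (444 and 2084). Parthenotes were higher than both IVF groups at 189 loci and lower at 8, with 146 and 14.7 for independent lists. The lower count depended on the setting: quantile normalization gave 171 higher and 84 lower loci, the fit without late 8-cell IVF replicate 1 gave 392 and 37, and no filter gave 21 and 1. With the parthenotes split, the counts were 11 and 0 (independent lists 6.85 and 3.59), or 122 and 6 (152 and 24.2), so the second split gave fewer shared loci than independent lists. The 8-cell IVF libraries, which have a request number of their own, were higher than both other groups at 59 loci and lower at 88, with 31.7 and 62.1 for independent lists. The direction of that split turned to 84 higher and 45 lower with a pseudocount of 5, and was 35 and 119 with a pseudocount of 0.1, 62 and 68 with median-of-ratios factors, 181 and 181 with quantile normalization, and 56 and 10 with no filter. With those libraries split the counts were 17 and 1 (independent lists 6.78 and 1.12), or 15 and 10 (6.05 and 6.11). In 100 simulations of unchanged groups no locus was shared in any of the 3 cases by limma. With each group difference removed few loci can be called at all. That result therefore says little about overlaps among groups that do differ, for which the independent lists and the splits are the closer measure.

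The fold changes of late against 8-cell IVF and of parthenotes against late 8-cell IVF correlated across loci at r = -0.94 (-0.54 in simulated unchanged groups), with a covariance of -1.39 against -0.049 simulated, both with the late libraries shared. For the comparisons that share the parthenotes, r was 0.08, under the simulated 0.39, and the covariance 0.039 against 0.031 simulated. For those that share 8-cell IVF, r was 0.27, under the simulated 0.54, and the covariance 0.146 against 0.049. Loci are not independent replicates, so these values describe the tables and carry no p-value.

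Positions of single libraries between the IVF stages were measured on all tested loci, with 0 at the 8-cell IVF mean and 1 at the late mean, and with each IVF library left out of its own mean. The 8-cell IVF libraries lay at 0.018 ± 0.0473 (SD, n = 8), the parthenotes at 0.080 ± 0.0936 (SD, n = 11) and the late libraries at 0.979 ± 0.401 (SD, n = 8). The difference between parthenotes and 8-cell IVF did not pass the threshold (0.061, exact permutation test, p = 0.112, adjusted p = 0.16 over 10 tests). Late 8-cell IVF replicate 1 lay at 0.0567 and the other late libraries at 0.875 to 1.31. The distance of a library from the mean of the rest of its group was 0.459 ± 0.0256 (SD, n = 8) in 8-cell IVF, as the root mean square over loci in log2 units. It was 0.577 ± 0.118 (SD, n = 11) in parthenotes and 0.773 ± 0.315 (SD, n = 8) in late 8-cell IVF. With the value of replicate 1 left out, the late mean was 0.668 ± 0.119 (SD, n = 7). Replicate 1 still entered the means from which those distances were taken. Libraries of parthenotes and of late 8-cell IVF were both more spread than those of 8-cell IVF (exact permutation test, adjusted p = 0.0114 and 0.00155 over 10 tests). The late test includes replicate 1, and distances within a group depend on each other, so these p-values are approximate. The late spread with replicate 1 removed from the means as well was not computed.

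**Figure D4:**
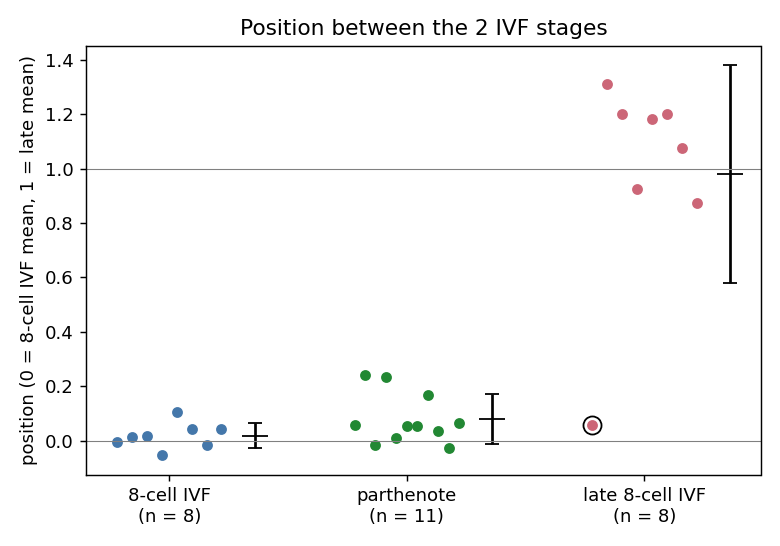
Position of each library between the mean of 8-cell IVF (0) and the mean of late 8-cell IVF (1) over 13461 loci, with points for libraries and bars for the mean ± SD of each group. The parthenotes span -0.026 to 0.241, the late libraries 0.875 to 1.31 apart from replicate 1 (ringed) at 0.0567.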

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

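Tests of explanations in this part were chosen after the values were seen. In 20 sets of 8 values (6 measures per library and 4 named loci, in each IVF group), 7 values lay far from the rest of their group, where chance flags about 1 set in 20. The parthenotes, with 11 libraries, were not examined this way.

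Late 8-cell IVF replicate 1 held 4 of the 7. Its distance from the rest of its group was 1.503 in log2 units (next 0.814), its position between the IVF stages 0.0567 (next 0.875), its log2(FPKM + 1) of MSTRG.6736 0.4916 (next 7.12) and that of MSTRG.28318 0 (next 6.95). A swap of labels with a library of another group analysed here would leave a late profile in that group. The highest position among the 19 libraries of the other groups was 0.241. Low depth would bring the library to the late range on abundant loci, but on 2282 loci with a mean of at least 10 FPKM its position was -0.024 (lowest other late library 0.877). RNA of a late embryo diluted with 8-cell RNA would keep most loci that rose above the 8-cell range. Of 2249 loci called at least 2-fold higher in the other 7 late libraries, 22.01% lay above each 8-cell IVF library in replicate 1. The share was 15.8% to 45.0% in parthenotes and 12.4% on average in a left-out 8-cell IVF library. It was 85.9% to 97.0% in the other late libraries, but the loci were picked on these, which raises their shares. These values argue against a swap with a library analysed here, low depth, and dilution of a profile still mostly late. A swap with a library not analysed here, a small share of late RNA, a single wrong label or an embryo of the late group that had not yet changed stay open and were not tested.

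The other 3 values came from 8-cell IVF libraries. Replicate 7 was high for MSTRG.6736, with a log2(FPKM + 1) of 0.7536 (next 0.17). Replicate 5 was high for MSTRG.28318, at 3.91 (next 1.38), and low for MSTRG.59787, at 3.791 (next 5.83).

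The run of 32 neighbouring loci lower in parthenotes than in 8-cell IVF was weighed as a second pattern. Across the 11 parthenotes these loci had a mean pairwise correlation of 0.616, against at most 0.138 in 1000 random sets matched on abundance, so they may be pieces of 1 source of reads and not 32 separate loci. Against 8-cell IVF libraries not used to pick the loci (26 picks), late 8-cell IVF was lower too. The median log2 difference was -1.193, or -0.764 relative to all loci. Late 8-cell IVF shares the request number of the parthenotes but also differs from 8-cell IVF in stage. Of the 13461 tested loci, 5923 were lower in late embryos, so the fall of the run does not separate the request number from the stage. Late 8-cell IVF replicate 1, of the parthenotes' request number, lay near 8-cell IVF in position (0.0567). Its mean over the run was 0.0071 FPKM, with 30 of the 32 loci at 0, against 0.752 to 3.26 FPKM in 8-cell IVF libraries. If its label is right, neither the late profile nor lack of a paternal genome would account for that low value. It is 1 library whose label is in doubt, so the value does not decide. Lack of a paternal genome would put parthenotes below late IVF embryos, and in parthenotes not used to pick the loci (41 picks) the median log2 difference was -0.145 as measured but -0.686 relative to all loci. The second value subtracts the median of the tested loci. Over all libraries that median was 0.55, but 0.13 under quantile normalization and 1.002 after rescaling to the same sum. With no filter it was 0.02, which loci at 0 in most libraries hold near 0. Of the 32 loci, 0 were called lower in parthenotes than in late 8-cell IVF. The answer depends on that median, and these 2 groups also differ in stage. Lack of a paternal genome therefore stays open beside the request number and a shared source of reads.

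The 289 loci higher in parthenotes than in 8-cell IVF were the third pattern weighed. In parthenotes not used to pick them, 349 picks, made once from each part of the parthenotes, differed from late 8-cell IVF, of the same request number, by -0.07 log2 relative to all loci (95% interval over loci -0.199 to 0.014) but by 0.476 as measured (0.348 to 0.561). A difference between request numbers alone would leave no difference there. Parthenotes and late embryos also differ in stage and breed cross, with 9560 loci called between them. The value relative to all loci rests on a median that was 0.55 as deposited, 0.13 under quantile normalization and 1.002 after rescaling to the same sum. The test therefore does not decide. If parthenotes were part of the way to the late profile, the late change of these loci would exceed the parthenote change. In parthenotes and 8-cell IVF libraries that were both not used to pick them, 47 loci were higher in late embryos by 0.621 log2 relative to all loci and in parthenotes by 0.847. The median difference per locus was -0.211 (-0.4 to -0.057), or -0.688 as measured (-0.877 to -0.535), where such an advance alone would give values above 0. The late change was taken with late 8-cell IVF replicate 1, which lay near 8-cell IVF and so would shrink it. It was not computed without that library, and the intervals are over loci, not libraries. Of the 55 picks behind the difference 44 came from 1 of the 4 splits, so it rests on few loci. The test therefore does not decide on such an advance. The request number stays open too, and the breed cross was not tested.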

How the results depend on the processing

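Testing each transcript, summing over transcripts, replicates 1 to 8 alone, leaving out the run of loci, overlaps without late 8-cell IVF replicate 1 or with no filter and positions on other loci were chosen after the data were seen. Gene lists, named symbols and the settings planned for them could not be run, since the loci have no names, and the settings planned for counts do not apply to FPKM. The 4 named loci kept their direction and side of the threshold in 8 of 8 settings in each comparison. Counts of loci past the threshold follow in the order late against 8-cell IVF, parthenote against 8-cell IVF and parthenote against late 8-cell IVF, from 8814, 361 and 9560. They were within 1.5 times of these values in 37, 27 and 37 settings, higher in 2, 5 and 2 and lower in 2, 10 and 2. Most of these settings left out 1 library, in part a library of a group outside the comparison, so they say less about the processing. No filter gave 14168, 90 and 15905 among 85161 loci, split into 7074 higher and 7094 lower, 33 and 57, and 8331 and 7574, so the imbalance between directions (2891 and 5923, 289 and 72, 6811 and 2749) shrank or turned. A filter of 5 FPKM gave 3273, 144 and 3378 among 4528 loci, a fold of at least 2 gave 5361, 203 and 5387, and each transcript tested gave 24940, 659 and 26307 among 35543 transcripts. The filters and transcripts changed the number tested. For parthenote against 8-cell IVF, quantile normalization gave 672, array weights 1693 and the 2 groups alone 1184, and the cause was not tested. Leaving out each library gave 8351 to 9600, 139 to 718 and 9132 to 10189 loci, and no locus called both ways changed sign. The 718, 9600 and 10189 all came without late 8-cell IVF replicate 1.

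The overlap of parthenotes apart from both IVF groups, 197 loci, was 115 with a pseudocount of 0.1, 112 after rescaling to a common sum, 116 with median-of-ratios factors, 22 with no filter and 429 without late 8-cell IVF replicate 1. That of 8-cell IVF apart from both other groups, 147 loci, was 362 with quantile normalization, 66 with no filter and 254 without that library. The total for late 8-cell IVF, 7725 loci, was within 1.5 times in 7 of 7 settings, with 8657 without that library and 11496 with no filter. Its split of 2430 higher and 5295 lower turned to 3001 and 2904 with quantile normalization and to 6325 and 5171 with no filter. The splits of the other overlaps also moved with the pseudocount or the scaling, up to 171 and 84 from 189 and 8 for parthenotes with quantile normalization, and to 84 and 45 from 59 and 88 for 8-cell IVF with a pseudocount of 5. For loci detected per library, the difference between parthenotes and 8-cell IVF passed at 0.1 FPKM (2305 loci) and 5 FPKM (324 loci), and that between parthenotes and late 8-cell IVF did not pass at 5 FPKM (154 loci). The cause was not tested in these cases.

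With the replicate number as a block, on replicates 1 to 8, the counts were 8650, 273 and 8887, against 8719, 327 and 8909 for the same libraries without it. Libraries with the same number did not deviate together: correlations ran from -0.02 to 0.14, -0.31 to 0.18 and -0.19 to 0.22, and 1, 1 and 3 of 8 libraries correlated best with their own number. The labels do not say what the number marks. The unknown total depth limits what can be said of loci near 1 FPKM.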

Other observations

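Tests of loci along the numbering and the values of single parthenotes were chosen after the data were seen, while the splits of libraries were planned.

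Loci with neighbouring numbers changed alike between the IVF stages. Across 4014 pairs of tested loci with consecutive numbers, the log2 fold changes of late against 8-cell IVF correlated at 0.46, with a highest value of 0.035 in 200 permutations of loci, and 72.5% of pairs had the same sign. The correlation was 0.15 at number differences of 2 to 5, 0.095 at 6 to 20, 0.049 at 21 to 100 and 0.018 beyond that up to 1000. Loci of 1 gene assembled in pieces, or reads that overlap both loci, would add to the first value, and these were not separated. Loci are not independent replicates.

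Among loci that passed the filter, the median change between the IVF stages correlated with the number of tested loci per window of the numbering. In 117 windows of 1000 locus numbers, the number of tested loci, 58 to 230, correlated with the median log2 fold change of late against 8-cell IVF at r = 0.61 and rho = 0.59 (permutation p = 1e-05 for both, the smallest that 100000 permutations give, 1 relation computed). Without the 2 windows farthest from the median the values were 0.58 and 0.58. Window medians ran from -0.83 to 0.25. Both measures depend on the filter, which 121 of 1096 loci that turned on and 770 of 865 that turned off passed. The median change of all loci was -0.45 with the filter. With no filter it was 0.00, but loci at 0 in most libraries hold it near 0. The relation was not computed with no filter, so it does not separate density along the numbering from the filter. Windows were permuted as if independent although neighbouring loci changed alike, so these p-values are approximate.

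Single parthenotes differed in position between the IVF stages. Replicates 2, 4 and 8 lay at 0.241, 0.236 and 0.169 and the other 8 at -0.026 to 0.064. Replicate 2 had 116 FPKM of MSTRG.28318 and 5.67 FPKM of MSTRG.6736, which are among the loci behind the position. MSTRG.6736 passed the filter only because replicate 2 was above 1 FPKM, so its value there is no independent observation. A locus on in late replicates 2 to 8 alone could enter the position only through a further library at 1 FPKM. Replicate 4 had the greatest distance from its group, 0.892 in log2 units.

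Each count of called loci was set against 100 splits of the compared libraries, the real one included, with the group sizes kept. Such splits cannot give a value below 1 in 100, and mixing unlike groups widens the spread within each part. The labels do not say that the libraries are independent, so the splits show only that the counts go with the group labels. In each comparison 1 split, the real one, gave as many loci. The real counts were 8814, 361 and 9560 and the highest of the other splits gave 6684, 25 and 10. The split with 6684 kept 7 late libraries together.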
